A study of Mus musculus with 34 samples.

How the data were processed

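RNA was sequenced from CD19+ cells sorted by FACS from the hearts of DTR transgenic mice, per the labels. The cells came in 2 gates, CD11b-negative and CD11b-positive, and the hearts were naive, injured with diphtheria toxin (DT), or injured and treated with pirfenidone (DT+PFD). There are 34 libraries: 8 naive, 6 DT and 3 DT+PFD libraries in each gate. The labels name 2 study batches, here set 1 and set 2. All DT+PFD libraries belong to set 1, which also holds 4 naive and 4 DT libraries per gate, while set 2 holds 4 naive and 2 DT libraries per gate. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between samples.

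Per the labels' protocols, cells were sorted into lysis buffer, cDNA was made from polyA RNA with a low-input kit and amplified for 12 cycles, and single reads of 50 bases were taken without strand information. Overlapping and antisense genes, close paralogs and immunoglobulin segments are therefore uncertain in their assignment. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 and TopHat for alignment to GRCm38 and HTSeq for counting. They also name DESeq, edgeR and limma without a version.

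The deposited table of counts holds whole HTSeq counts for 46078 genes, of which 32238 have reads. A second deposited table holds for 6500 genes a score that per the labels is depth-normalized, batch-corrected and filtered on CPM (counts scaled to library size). Of its values 1474 (0.667 percent) lie below 0, in 487 genes. That score was used only in 1 alternative, on the log2 scale above a floor of 10, where 1659 values lay at the floor. All columns were matched to the labels. Symbols were missing for 197 genes and 193 of them were filled from the Ensembl identifier, and 270 symbols belong to more than 1 identifier. Of 45036 genes with a position in the table and in the annotation of GRCm38, 39311 had the same start after adding 1 and 257 without adding, so starts are printed 1-based, with 1 added.

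Each library holds 9297579 to 27529492 counted reads (median 16677000) and 16018 to 22757 detected genes (median 18889). Mitochondrial genes take 1.594 to 28.59 percent of the counts. Replicates differ far beyond sampling noise, with a chi-square per degree of freedom of at least 17.34 between any pair in a group, so the spread between samples and not the depth sets the precision. The common biological coefficient of variation is 0.854. The median standard error of a log2 change is 0.5934 for DT against naive in the CD11b-negative gate and 0.7915 for DT+PFD against DT in the CD11b-positive gate.

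The tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. All 34 libraries entered 1 fit with a term for each of the 6 groups and a term for the set. Genes were filtered with filterByExpr, leaving 18251. Size factors came from TMM, dispersion from estimateDisp, and the test was edgeR's quasi-likelihood test with robust=TRUE and Benjamini-Hochberg adjustment over all genes tested. A gene passed at an adjusted p under 0.05, and every adjusted p for a gene in the report comes from this test unless another is named. Levels are in CPM with TMM size factors, given as mean ± SD over libraries, and log2 changes are estimates of the fit.

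The 11 comparisons were DT against naive, DT+PFD against DT and DT+PFD against naive in each gate, CD11b-positive against CD11b-negative cells in each condition, and the difference between the gates in the effect of injury and in that of pirfenidone. Gene groups were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with a correlation estimated from the data, and fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. The median and mean of a list are taken over its tested members, and "adjusted over the list alone" means that the p-values of its members were adjusted without the other genes.

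The 29 lists hold 396 genes. They are B cell identity, follicular (mature recirculating) B cells, B-1 cells, marginal zone B cells, immature and transitional B cells, germinal centre B cells, plasma cells, antigen receptor activation, immediate early and dissociation-induced genes, type I interferon response, MHC class II presentation, cytokines and chemokines, trafficking receptors and integrins, NF-kB and Toll-like receptor genes, cell cycle, oxidative phosphorylation, glycolysis and hypoxia, TGF-beta pathway and targets, p53 targets and apoptosis, and ribosomal proteins. Markers of other cells are those of monocytes and macrophages, neutrophils, dendritic cells, T and NK cells, cardiomyocytes, fibroblasts, endothelial cells, pericytes and smooth muscle, and erythroid cells and platelets. The score of a list in a library is the mean log2 CPM of its genes with an offset of 1.

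The comparisons, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. In each comparison the text names the 10 genes with the smallest p in each direction among those that pass. Where fewer than 3 pass in a direction, the 3 with the smallest p are given and said not to pass. Immunoglobulin and T cell receptor segments, predicted models and pseudogenes were left out of this naming and only counted. From each list up to 4 members with the smallest adjusted p under 0.05 were added. Cd19, Itgam, Cd79a, Ms4a1, Tgfb1, Tnf, Il1b, Il6, Il10 and Ccl7 were looked at in every comparison. A gene is said to hold in both sets only where its sign is the same in the fits of set 1 and of set 2. Serp2 meets the rule but is at 0 in one group, so no fold is given for it.

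Other choices fixed beforehand were DESeq2 and limma-voom with sample quality weights as other tests, DESeq2's size factors, robust=FALSE, no filter on low counts, a stricter filter of over 1 CPM in at least 8 libraries, no set term, each set alone, the libraries of the compared groups alone, a replicate block, a test against a fold of 1.5 (glmTreat), limma on the deposited score, and each library left out in turn. The rule on library quality removed 0 libraries and so tried nothing. Further alternatives were chosen after seeing the data: without the naive set 1 libraries labelled 1 and 2, set 1 without them, without the naive CD11b-positive libraries of set 2, covariates for the myeloid score, the mitochondrial share and the fibroblast score, and for the gates a block that also pairs the consecutive numbers of set 1.

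In set 2 the own sample number gave the best correlation between gates for all 4 naive numbers (0.38, 0.21, 0.41 and 0.11 for 5a to 8a), over 4237 genes with group means removed. The 2 DT numbers are mirror images once the means are removed and so make 1 comparison (0.15). Numbers are not shared between the gates in set 1. Of its 11 pairs of consecutive numbers 7 correlate best with each other (all 11 from -0.68 to 0.5), so whether these are pairs is open. The replicate block pairs the set 2 libraries and holds set 1 as 1 block, and by construction it takes up the difference between naive and DT in set 2.

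The procedure was tested on simulated data with the dispersion and depth of these libraries, with 50 genes changed at each fold among 18251. For DT against naive in the CD11b-negative gate, 16 percent of genes changed by a fold of 2 were recovered, 66 percent at a fold of 4, and 84 percent at a fold of 16, with 6.45 percent false calls among 124. For DT+PFD against DT in the CD11b-positive gate it was 6 percent at a fold of 2, 32 percent at 4 and 64 percent at 16, with no such gap at a fold of 8 (66 percent in both). Genes that did not pass are therefore not shown to be unchanged. Other splits of the libraries, 60 per comparison and 10 for the DT+PFD gates, were counted with the same test, and outside the gate comparisons they ignore the set. Splits that keep the sets, 35 or 60 per comparison, were chosen after seeing the data. The shared DT libraries in the injury and pirfenidone effects were handled by dividing them into disjoint parts and by 200 simulations of unchanged groups.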

Results

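How injury with diphtheria toxin changes CD19+ cells of the heart was asked first in the CD11b-negative gate. Il7r rose from 2.45 ± 1.46 (SD, n = 8) CPM in naive to 66.0 ± 35.5 (SD, n = 6) CPM in DT libraries, a log2 change of 4.76 (SE 0.62, adjusted p = 0.00017, above the naive median in 6 of 6). Il7r (ENSMUSG00000003882, chromosome 15, 9506161 to 9529876) encodes the receptor chain through which interleukin-7 acts on early lymphocytes. Ptpn22 (ENSMUSG00000027843, chromosome 3, 103859795 to 103912247), a phosphatase that restrains antigen receptor signalling, rose from 157 ± 26.4 (SD, n = 8) to 508 ± 150 (SD, n = 6) CPM, a log2 change of 1.65 (adjusted p = 0.0012, 6 of 6, block adjusted p = 0.052). Fcer2a (ENSMUSG00000005540, chromosome 8, 3681737 to 3694174), which encodes the IgE receptor CD23 of mature B cells, fell from 1030 ± 265 (SD, n = 8) to 276 ± 146 (SD, n = 6) CPM, a log2 change of -2.02 (adjusted p = 0.019, below the naive median in 6 of 6, block adjusted p = 0.2). Its change was -1.56 in set 1 and -2.51 in set 2.

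Of 18251 genes, 37 rose and 49 fell in DT against naive CD11b-negative cells. The 10 with the smallest p among those that rose are Il7r, Timp1, Arg1, Ptpn22, Serpina3n, Spp1, Pde2a, Flrt3, Ppp1r21 and RP23-110C17.2. Arg1, the arginase of alternatively activated macrophages, rose from 0.796 ± 0.424 (SD, n = 8) to 81.7 ± 110 (SD, n = 6) CPM (log2 6.41, adjusted p = 0.00032, 5 of 6). Spp1, which encodes osteopontin, rose from 9.92 ± 11.9 (SD, n = 8) to 649 ± 844 (SD, n = 6) CPM (log2 5.88, adjusted p = 0.0018, 6 of 6). Timp1 and Serpina3n, whose source is open, rose by 6.75 and 6.24 on the log2 scale. Pde2a, a phosphodiesterase, rose by 1.84 on that scale.

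The 10 genes with the smallest p among those that fell in the CD11b-negative gate are Rhoa, Calr, Adgre5, Itgb7, Snrnp25, Ndufa13, Psme1, Ifi35, Ifi27l2a and Lsp1. Adgre5, the adhesion receptor CD97, changed by -1.03 on the log2 scale, from 391 ± 55 (SD, n = 8) to 191 ± 61.3 (SD, n = 6) CPM. Itgb7 changed by -1.94 and the interferon-induced Ifi27l2a by -2.13. Lsp1 went from 1280 ± 161 (SD, n = 8) to 565 ± 204 (SD, n = 6) CPM (log2 -1.20, adjusted p = 0.012, block adjusted p = 0.11).

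Among the lists in the CD11b-negative gate, the MHC class II list fell as a group (median log2 -0.7, adjusted p = 2.3e-12, adjusted p = 0.052 with an estimated correlation). None of its 10 genes passed over all genes and 7 fell adjusted over the list alone. The type I interferon list fell too (median -0.97, adjusted p = 4.8e-10, adjusted p = 0.052 with an estimated correlation). Of its 17 genes Bst2 fell over all genes and 5 adjusted over the list alone. B cell identity genes fell (median -0.59, adjusted p = 1.1e-10, adjusted p = 0.17 with an estimated correlation), with 0 of 17 passing singly and 4 adjusted over the list alone. In the follicular list Fcer2a and Cd55 fell and 7 of 9 did not pass (median -0.53, adjusted p = 2.3e-08, adjusted p = 0.065 with an estimated correlation), and 3 fell adjusted over the list alone. The TGF-beta list rose (median 0.46, adjusted p = 0.00013, adjusted p = 0.052 with an estimated correlation). Pmepa1, a TGF-beta target, is its only gene over all genes, with 4 of 15 adjusted over the list alone, while Tgfb1 itself stood at 7.16 ± 1.09 (SD, n = 6) against 5.93 ± 1.8 (SD, n = 8) CPM and did not pass.

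Camera's test also passed for 6 further lists of genes in this gate. Marginal zone genes fell (median -0.44, adjusted p = 0.00032, adjusted p = 0.052 with an estimated correlation), with 0 of 9 passing singly and 1 adjusted over the list alone. Trafficking genes fell (median -0.2, adjusted p = 0.0046, adjusted p = 0.15 with an estimated correlation), with Itgb7 of 16 over all genes and 3 adjusted over the list alone. Oxidative phosphorylation genes fell (median -0.27, adjusted p = 0.0023, adjusted p = 0.17 with an estimated correlation) and ribosomal protein genes fell (median -0.15, adjusted p = 0.0046, adjusted p = 0.61 with an estimated correlation), with none passing singly. Cytokine genes rose as a list (median 0.48, adjusted p = 0.023, adjusted p = 0.55 with an estimated correlation) with none passing singly. Without the naive set 1 libraries 1 and 2, a choice made after seeing the data, the cytokine median is 2 with 7 genes higher (adjusted p = 0.022 with an estimated correlation), and the trafficking list no longer passes (adjusted p = 0.25). Fibroblast markers rose (median 2.4, adjusted p = 3.8e-06, adjusted p = 0.24 with an estimated correlation), with 0 of 10 over all genes and 6 adjusted over the list alone.

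Other lists of the CD11b-negative gate did not pass, or passed against the sign of their genes. Monocyte and macrophage markers have a median of -0.63 and a mean of -0.44, while camera ranks them higher than other genes (adjusted p = 0.00071, adjusted p = 0.55 with an estimated correlation). When both libraries are left out, 15 of those 19 markers rose and the median is 4.5. Neutrophil markers then turn from a median of -1.5 to 3.5 with 7 of 13 higher (adjusted p = 8.3e-11, adjusted p = 0.051 with an estimated correlation), and the dendritic (median 1.4, adjusted p = 0.0032) and germinal centre lists (1.2, adjusted p = 0.03) pass, though not with an estimated correlation (adjusted p = 0.066 for each). Genes of lists that did not pass camera's test include Flt3 of dendritic cells (log2 2.50), Il7r of T and NK cells, Ppbp of platelets (5.36), Bnip3 of glycolysis and hypoxia (1.34) and Relb of NF-kB (0.94), all of which rose, and Cd40 of NF-kB, which fell (-1.09). Those lists have medians of 0.3 (dendritic), 0.76 (T and NK), -0.18 with a mean of 0.61 (erythroid and platelet), 0.0058 (glycolysis) and -0.036 (NF-kB). No gene passed in the B-1 list (median 0.17, mean -0.0095), the immature (-0.5), germinal centre (0.56) and plasma lists (-0.19), or antigen receptor activation (-0.13). The same holds for immediate early (-0.27), cell cycle (-0.085) and p53 genes (0.22), and for neutrophil (-1.5), cardiomyocyte (0.0012), endothelial (1.3) and pericyte markers (1.1).

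Of the genes looked at in every comparison, none passed between DT and naive CD11b-negative cells. Ms4a1, which encodes CD20, stood at 846 ± 421 (SD, n = 6) against 1690 ± 420 (SD, n = 8) CPM (log2 -1.23, adjusted p = 0.078). Cd19 stood at 1850 ± 783 (SD, n = 6) against 2630 ± 730 (SD, n = 8) CPM (log2 -0.69, adjusted p = 0.32). Cd79a, Itgam, Tnf, Il1b, Il6, Il10 and Ccl7 did not pass either. The number of genes rests on the libraries used, with 0 in set 1 alone, 339 in set 2 alone and 372 without the naive library labelled 2. With the replicate block 28 genes pass, and 13 of the 29 named genes that pass do so there, Il7r and Arg1 among them (block adjusted p = 0.014 for each).

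In the CD11b-positive gate the same question gave genes headed by Hilpda. Hilpda (ENSMUSG00000043421, chromosome 6, 29272488 to 29275446), a hypoxia-induced inhibitor of lipid breakdown, rose from 38.8 ± 8.71 (SD, n = 8) to 221 ± 160 (SD, n = 6) CPM (log2 2.48, SE 0.23, adjusted p = 5.5e-08, 6 of 6, block adjusted p = 7.9e-05). Its change is 2.00 in set 1 and 3.17 in set 2. Arg1 (ENSMUSG00000019987, chromosome 10, 24915208 to 24927470) rose from 0.878 ± 0.25 (SD, n = 8) to 318 ± 317 (SD, n = 6) CPM (log2 8.40, adjusted p = 8.7e-06, 6 of 6). Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), a transcription factor of the interferon response, fell from 155 ± 80.9 (SD, n = 8) to 69.3 ± 24.4 (SD, n = 6) CPM (log2 -0.95, adjusted p = 0.0099, block adjusted p = 0.12). Fcer2a fell from 539 ± 249 (SD, n = 8) to 110 ± 85.2 (SD, n = 6) CPM (log2 -2.39, adjusted p = 0.0045, block adjusted p = 0.078).

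Of 18251 genes, 143 rose and 104 fell in DT against naive CD11b-positive cells, with 13 immunoglobulin segments up and 3 down. The named genes that rose are Hilpda, Arg1, Rbm3, Timp1, Serpina3n, Aprt, RP23-110C17.2, Spp1, Plet1 and Plec. Rbm3, an RNA-binding protein induced by cold, rose from 228 ± 39.3 (SD, n = 8) to 641 ± 175 (SD, n = 6) CPM. Spp1 rose from 29.7 ± 15.2 (SD, n = 8) to 1610 ± 1140 (SD, n = 6) CPM and Fn1, which encodes fibronectin, from 43 ± 21.9 (SD, n = 8) to 540 ± 350 (SD, n = 6) CPM. The named genes that fell are Adgre5, Samd9l, Cd55, Uba7, Itgal, Fcer2a, Il27ra, Irf9, Add3 and Slc15a4. Cd55 changed by -2.13 on the log2 scale, Il27ra by -2.76 and Itgal by -1.42.

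Glycolysis and hypoxia genes rose as a group in the CD11b-positive gate (median log2 0.67, adjusted p = 1.7e-10, adjusted p = 0.014 with an estimated correlation, fry p adjusted to 7.7e-05). Of 16 genes, 6 rose over all genes, 9 adjusted over the list alone, and none fell. Pkm, the pyruvate kinase gene, rose from 804 ± 163 (SD, n = 8) to 1820 ± 865 (SD, n = 6) CPM (log2 1.19, adjusted p = 0.0015, 5 of 6, block adjusted p = 0.1) and Pgam1 from 59.3 ± 21.2 (SD, n = 8) to 111 ± 45.8 (SD, n = 6) CPM (log2 1.02, adjusted p = 0.0052, block adjusted p = 0.11). Ldha and Gapdh rose by 0.68 and 0.67 on the log2 scale. The type I interferon list fell (median -1.2, adjusted p = 4.7e-12, adjusted p = 0.014 with an estimated correlation). Irf7 and Stat1 are its 2 of 17 genes over all genes, and 7 fell adjusted over the list alone. The interferon-related Irf9, Samd9l and Uba7 outside the list fell as well.

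Follicular genes fell in this gate (median -0.95, adjusted p = 4.2e-13, adjusted p = 0.014 with an estimated correlation), with Cd55, Fcer2a and Cr2 of 9 over all genes and 6 adjusted over the list alone. B cell identity genes fell (median -0.73, adjusted p = 1.4e-12), with Cd72 and Ralgps2 of 17 over all genes and, adjusted over the list alone, 11 that fell and 1 that rose. MHC class II genes fell (median -0.55, adjusted p = 5.1e-09), with H2-Ob of 10 over all genes and 6 adjusted over the list alone. Trafficking genes fell (median -0.39, adjusted p = 0.0019), with Itgal over all genes. Marginal zone genes fell (median -0.23, adjusted p = 0.021), with Cr2 and Notch2 over all genes. Plasma cell genes rose as a list with none passing singly (median 0.76, adjusted p = 0.014). Apart from follicular genes these lists have an adjusted p from 0.11 to 0.38 with an estimated correlation.

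TGF-beta genes (median 0.49, adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation) and p53 genes (median 0.61, adjusted p = 0.02, adjusted p = 0.068 with an estimated correlation) rose as lists without a gene that passed over all genes. Cardiomyocyte markers fell (median -1.8, adjusted p = 0.00032, adjusted p = 0.44 with an estimated correlation). Fibroblast markers rose (median 1.5, adjusted p = 0.0024, adjusted p = 0.48 with an estimated correlation), as did pericyte and smooth muscle markers (median 1.4, adjusted p = 0.031, adjusted p = 0.58 with an estimated correlation). Monocyte and macrophage markers did not pass as a list (median -0.33, mean 0.015), nor did neutrophil markers (median -0.56). Cell cycle genes have a median of 0.15 and a mean of -0.059, oxidative phosphorylation genes 0.13 and -0.0049, and neither passed. Of other genes named from lists, Nr4a2, Flt3 and Il7r rose and Cd40 fell. Leaving out the naive set 1 libraries 1 and 2 ends the calls of the plasma (adjusted p = 0.052), p53 (0.052) and pericyte lists (0.19), and of the genes Cd72, Ralgps2, Notch2, Nr4a2 and Stat1 (0.051 to 0.083).

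Mitochondrial genes take 14.9 ± 10.6 (SD, n = 8) percent of the counts in naive and 4.85 ± 2.61 (SD, n = 6) percent in DT CD11b-positive libraries, and within naive libraries 5.90 ± 4.36 (SD, n = 4) percent in set 1 and 23.8 ± 5.47 (SD, n = 4) percent in set 2. Cd19 stood at 865 ± 532 (SD, n = 6) against 1490 ± 719 (SD, n = 8) CPM (log2 -0.92, adjusted p = 0.075), and Ms4a1 (log2 -1.19, adjusted p = 0.053), Itgam, Tgfb1 and Il1b did not pass. Of the 36 named genes 14 pass with the replicate block, where 22 genes are called. Set 1 alone calls 3 genes, and without the naive CD11b-positive libraries of set 2, an alternative chosen after seeing the data, 50 pass.

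**Figure D1:**
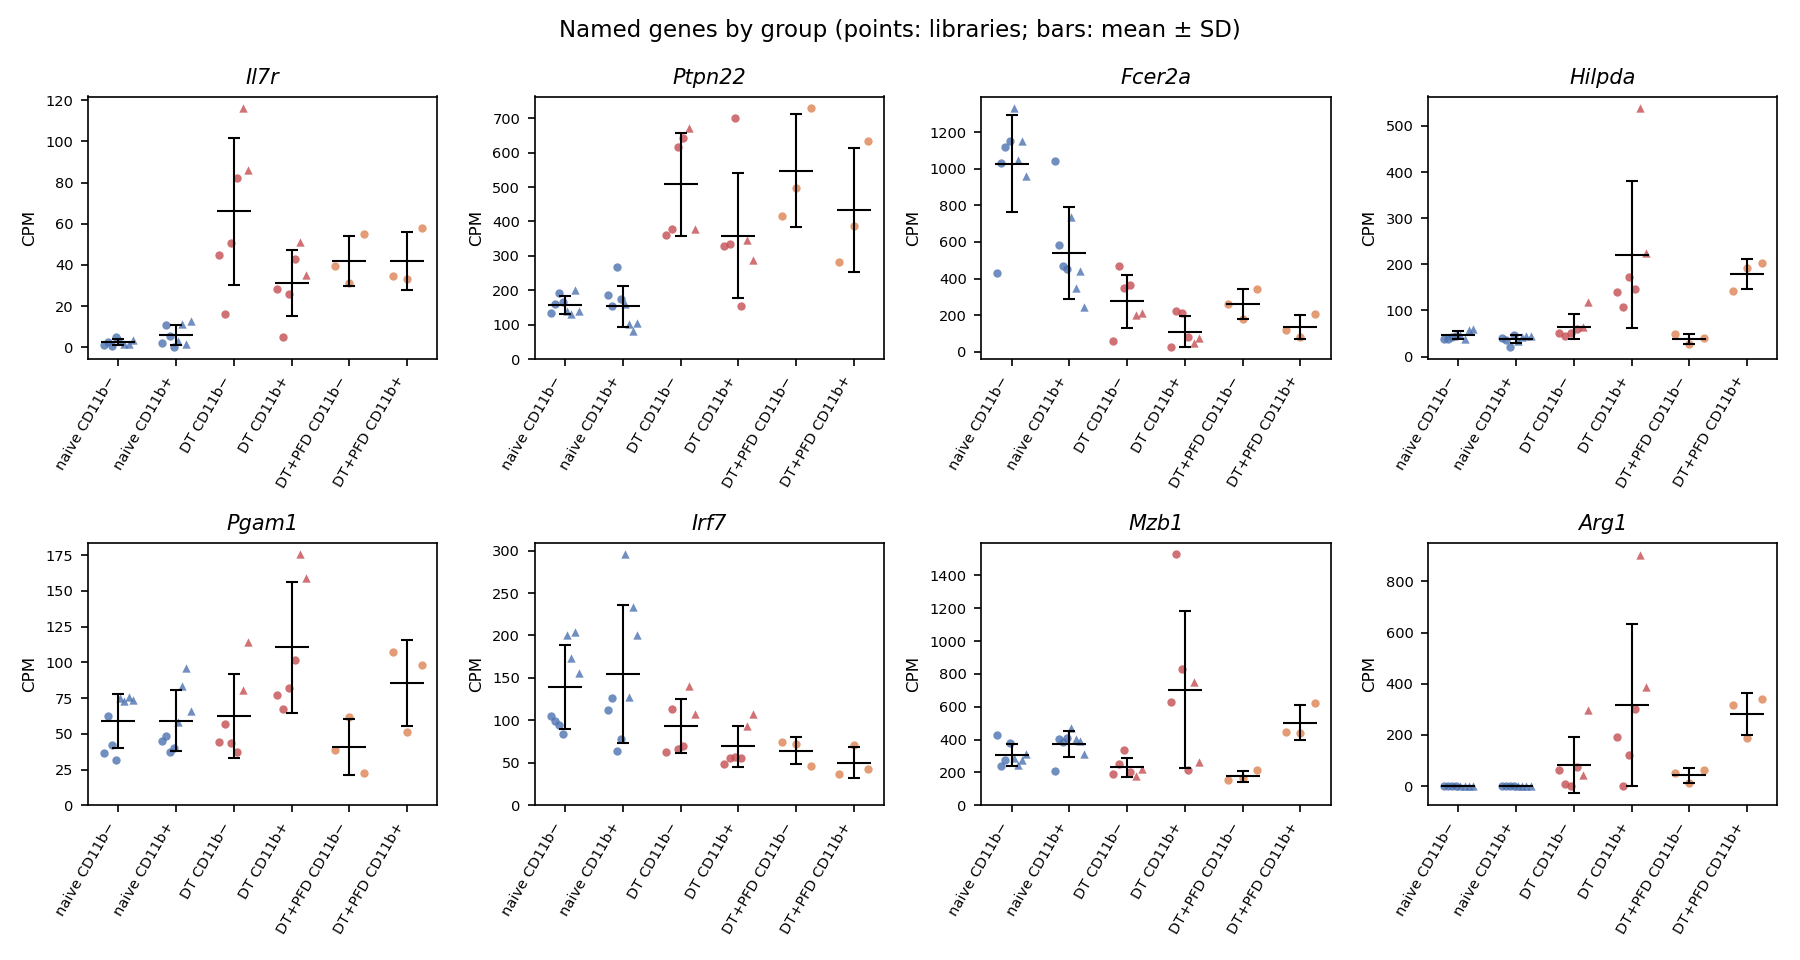
Levels (CPM, linear scale) of 8 named genes in the 6 groups, with mean ± SD, points for libraries, circles for set 1 and triangles for set 2. Hilpda stands at 221 CPM in DT and 38.8 CPM in naive CD11b-positive cells, and Fcer2a at 276 and 1030 CPM in DT and naive CD11b-negative cells.

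Whether injury acts differently in the 2 gates was tested as a difference of effects. Hilpda has a larger rise in CD11b-positive than in CD11b-negative cells, by 1.94 on the log2 scale (SE 0.32, adjusted p = 0.015, block adjusted p = 0.02), from changes of 2.48 and 0.55. Igkv1-117 and Igkv4-90, immunoglobulin light chain variable segments, also passed, by 3.47 and 6.97. They are named here after their values were seen, since segments fall outside the naming rule. No gene passed in the other direction. Glycolysis and hypoxia genes differ as a list (median 0.5, adjusted p = 6.4e-08, adjusted p = 0.086 with an estimated correlation), with 0 of 16 over all genes and 5 adjusted over the list alone. Plasma cell genes (median 1.1, adjusted p = 5.2e-05, adjusted p = 0.28 with an estimated correlation) and oxidative phosphorylation genes (median 0.32, adjusted p = 0.005, adjusted p = 0.38 with an estimated correlation) are higher in this difference and follicular genes lower (median -0.5, adjusted p = 0.027, adjusted p = 0.97 with an estimated correlation). The call of 3 genes becomes 0 without DT CD11b-negative set 2 library 1, without the naive CD11b-positive libraries of set 2, with limma-voom, with the deposited score, against a fold of 1.5, in set 1 alone and with consecutive set 1 numbers also paired in the block, and 42 with DESeq2. Without the naive set 1 libraries 1 and 2 it becomes 51, the follicular list no longer passes (median -0.21, adjusted p = 0.26), the plasma median is 0.52, and the medians of monocyte, neutrophil and cytokine lists turn to -4.8, -4.2 and -1.3 (adjusted p = 0.019, 0.051 and 0.14 with an estimated correlation).

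What pirfenidone changes in injured hearts was asked next, and no gene passed in CD11b-negative cells. Stat3, which carries signals of interleukin-6 type cytokines, stood at 552 ± 118 (SD, n = 3) CPM in DT+PFD and 415 ± 195 (SD, n = 6) CPM in DT libraries (log2 0.82). Ifit2, an interferon-induced gene, stood at 0.813 ± 0.671 (SD, n = 3) against 9.44 ± 6.4 (SD, n = 6) CPM (log2 -3.51), and Il10 at 0.288 ± 0.124 (SD, n = 3) against 6.15 ± 4.85 (SD, n = 6) CPM (log2 -4.78). The genes with the smallest p were Stat3, Rgl2 (0.98) and Qprt (3.33) with higher values and Sec13 (-0.62), Ifit2 and Mrpl11 (-1.14) with lower values, none of which passed (adjusted p = 0.93). The counts are 0 with edgeR, where 914 genes have an unadjusted p under 0.05, 104 with DESeq2 (5 up, 99 down) and 4 with limma-voom (3 up, 1 down).

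Camera's test with its preset correlation passed for 9 lists of genes in this comparison, none of which passes with an estimated correlation (adjusted p from 0.53 to 0.65) or with fry (0.35 to 0.67). Ribosomal protein genes fell (median -0.46, adjusted p = 1.9e-08), as did oxidative phosphorylation genes (median -0.43, adjusted p = 4e-04). Immediate early genes fell (median -0.79, adjusted p = 4e-04), as did interferon genes (median -0.58, adjusted p = 8e-04). Cytokine genes (median -0.81, adjusted p = 0.028) and glycolysis genes (median -0.2, adjusted p = 0.044) fell as lists. Markers of cardiomyocytes (median -2.3, adjusted p = 1.8e-05), fibroblasts (median -2.3, adjusted p = 0.006) and endothelial cells (median -2.8, adjusted p = 0.0024) fell as well. Without the naive set 1 libraries 1 and 2 the glycolysis call ends (adjusted p = 0.055) and the cytokine median is -0.5. The other 20 lists did not pass.

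In CD11b-positive cells under pirfenidone 18 genes rose and 24 fell, including 5 immunoglobulin segments up and 2 down. Pim2 (ENSMUSG00000031155, chromosome X, 7878262 to 7883432), a kinase that promotes lymphocyte survival, rose from 56.1 ± 19.1 (SD, n = 6) to 150 ± 47.7 (SD, n = 3) CPM (log2 1.5, adjusted p = 0.036, 3 of 3, block adjusted p = 0.11). Pigh (ENSMUSG00000021120, chromosome 12, 79080673 to 79089670), which acts in the first step of GPI anchor synthesis, fell from 9.01 ± 5.08 (SD, n = 6) to 0.106 ± 0.128 (SD, n = 3) CPM (log2 -6.20, adjusted p = 0.0091, block adjusted p = 0.042). Usp18, which removes ISG15 and damps interferon signalling, fell from 23.3 ± 13.6 (SD, n = 6) to 1.18 ± 1.09 (SD, n = 3) CPM (log2 -4.30, adjusted p = 0.032, block adjusted p = 0.083). The other named genes that rose are Nipal4, Dusp12, Slc35f2, Pigl, Xndc1, Zmat1, Zfp942, Lemd3 and Slfn8, where Nipal4 and Slc35f2 rest on 1 library. The others that fell are Tgs1, Kctd18, P2ry14, Trib3, Suox, Stx1a, Smagp and Rdx.

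The interferon list fell in this comparison (median -1.2, adjusted p = 0.0027, adjusted p = 0.97 with an estimated correlation), with Usp18 of 17 over all genes and 3 adjusted over the list alone. B cell identity genes rose (median 0.33, adjusted p = 0.015, adjusted p = 0.97 with an estimated correlation) and cardiomyocyte markers fell (median -1.4, adjusted p = 0.041, adjusted p = 0.97 with an estimated correlation). Of single B cell genes Cd19 stood at 1420 ± 369 (SD, n = 3) against 865 ± 532 (SD, n = 6) CPM and did not pass (adjusted p = 0.49), and Tgfb1 and Il10 did not pass. The other 26 lists did not pass. The count of 42 genes is 0 in set 1 alone, 0 with only the compared groups in the fit, 0 with limma-voom and 519 with DESeq2. It becomes 831 without DT+PFD CD11b-positive library 17 and 4 without library 19. A replicate block leaves 7 genes, and 3 of the 20 named genes pass with it.

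No gene passed for a difference of the pirfenidone effect between the gates. Pigh has the smallest adjusted p (log2 -6.69, SE 1.2, adjusted p = 0.082), followed by Stx1a (-8.34, adjusted p = 0.13) and Trib3 (-5.96, adjusted p = 0.13), and none of the 29 lists passed, with 0.067 as the smallest adjusted p of ribosomal and fibroblast genes. Beside 0 genes with edgeR, 1092 have an unadjusted p under 0.05 and DESeq2 calls 91 (41 up, 50 down). Without DT+PFD CD11b-positive library 17 the count is 229.

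Whether genes changed by injury move back under pirfenidone was measured as the covariance of both effects over 18251 genes. With DT libraries divided into disjoint parts the covariance is 0.107 in CD11b-negative cells (SD 0.085 over 20 divisions, simulated range -0.275 to 0.28) and 0.0603 in CD11b-positive cells (SD 0.136, simulated range -0.542 to 0.546). With the same DT libraries in both effects it is -0.0867 and -0.244, where unchanged groups give -0.161 and -0.315 by simulation. Against naive CD11b-positive cells Hilpda changed by 2.48 in DT and 2.50 in DT+PFD hearts and Arg1 by 8.40 and 8.86 on the log2 scale.

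How DT+PFD hearts differ from naive hearts was asked in CD11b-negative cells, where 31 genes rose and 79 fell. Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540) rose from 229 ± 76.2 (SD, n = 8) to 552 ± 118 (SD, n = 3) CPM (log2 1.78, SE 0.21, adjusted p = 2.5e-05, 3 of 3, block adjusted p = 0.00085). Il7r rose from 2.45 ± 1.46 (SD, n = 8) to 41.8 ± 12.1 (SD, n = 3) CPM (log2 4.38, adjusted p = 0.0022) and Ptpn22 from 157 ± 26.4 (SD, n = 8) to 548 ± 164 (SD, n = 3) CPM (log2 1.64, adjusted p = 0.012, block adjusted p = 0.052). Crip1 fell from 448 ± 97.9 (SD, n = 8) to 111 ± 23.7 (SD, n = 3) CPM (log2 -1.77, adjusted p = 0.0067). The other named genes that rose are Arg1, Pde2a, Timp1, Spp1, Ssh2, Itgb3 and Tbc1d15. Those that fell are Sec13, Capg, Tbca, Ndufs8, Ndufa13, Psmb1, Park7, Atp5e and Tomm7, of which Ndufs8, Ndufa13, Atp5e and Tomm7 act in mitochondria.

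Oxidative phosphorylation genes fell in this comparison (median -0.77, adjusted p = 8e-07, adjusted p = 0.037 with an estimated correlation), with 0 of 14 over all genes and 8 adjusted over the list alone. Interferon genes fell (median -1.5, adjusted p = 4.1e-11, adjusted p = 0.037 with an estimated correlation), with Rtp4 of 17 over all genes and 4 adjusted over the list alone. Ribosomal protein genes (median -0.61, adjusted p = 1.9e-10) and MHC class II genes (median -0.85, adjusted p = 1.9e-07) fell, with 14 and 7 adjusted over the list alone. Immediate early genes fell (median -1.1, adjusted p = 0.00015) with Klf6 over all genes, and Nr4a1, an early gene of antigen receptor signalling, fell from 3050 ± 949 (SD, n = 8) to 1140 ± 192 (SD, n = 3) CPM. Follicular (median -0.66, adjusted p = 2.5e-05) and B cell identity genes (median -0.73, adjusted p = 5.8e-05) fell as lists. These 5 lists have an adjusted p from 0.26 to 0.48 with an estimated correlation. TGF-beta genes rose (median 0.45, adjusted p = 0.00037, adjusted p = 0.071 with an estimated correlation), with Pmepa1 over all genes. Plasma (median -0.63), marginal zone (-0.87) and cardiomyocyte genes (-2.6) fell as lists with adjusted p = 0.44, 0.26 and 0.33 with an estimated correlation. Leaving out the naive set 1 libraries 1 and 2 ends the plasma call (median -0.18, adjusted p = 0.084) and that of oxidative phosphorylation genes with an estimated correlation (adjusted p = 0.056), and moves the medians of marginal zone genes to -0.37, of TGF-beta genes to 0.74 and of monocyte markers to 4.3. Neutrophil (median from -2.5 to 2.7), fibroblast (-0.22 to 1.3) and cytokine lists (-0.48 to 0.17) then pass, with adjusted p from 0.14 to 0.59 with an estimated correlation. Monocyte markers have a median of -1 and rank high in camera's test (adjusted p = 0.0025, adjusted p = 0.73 with an estimated correlation). Without DT+PFD CD11b-negative library 20 the call is 4 genes, and without the naive library labelled 2 it is 313. Of the 25 named genes 18 pass with the replicate block, where 39 are called.

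In CD11b-positive cells of DT+PFD against naive hearts 227 genes rose and 128 fell, with 13 immunoglobulin segments up and 3 down. Hilpda rose from 38.8 ± 8.71 (SD, n = 8) to 179 ± 31.3 (SD, n = 3) CPM (log2 2.50, adjusted p = 2.9e-06, 3 of 3, block adjusted p = 3.3e-05). Irf9, which joins STAT1 and STAT2 in the interferon response, fell from 178 ± 37.4 (SD, n = 8) to 50.9 ± 9.1 (SD, n = 3) CPM (log2 -1.74, adjusted p = 0.0022, block adjusted p = 0.002). The other named genes that rose are Arg1, Timp1, Spp1, Rbm3, Frrs1, Stat3, Zbtb43, Nipal4 and Slc37a2, where Nipal4 turns to -0.192 without DT+PFD library 21. Those that fell are Pigh, Usp18, Rdx, Usf1, Trib3, Mdh1, Kctd18, Smagp and Rnf31. The interferon list fell (median -2.8, adjusted p = 1.2e-13, adjusted p = 0.023 with an estimated correlation), with 6 of 17 over all genes and 11 adjusted over the list alone. Of these, Usp18 went from 52.4 ± 27.1 (SD, n = 8) to 1.18 ± 1.09 (SD, n = 3) CPM, Ifit2 from 36.2 ± 24.8 (SD, n = 8) to 1.92 ± 1.41 (SD, n = 3) CPM, Mx1 changed by -5.33 and Xaf1 by -3.52 on the log2 scale.

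Follicular genes fell in the same comparison (median -1.1, adjusted p = 1.4e-05), with Fcer2a and Cd55 of 9 over all genes and 5 adjusted over the list alone. MHC class II (median -0.64, adjusted p = 0.001) and immediate early genes (median -0.73, adjusted p = 0.0079) fell with none over all genes. Glycolysis genes have a median of 0.32 and a mean of -0.048 and rank higher (adjusted p = 0.0078), with Pkm and Pgam1 over all genes. TGF-beta genes rose (median 0.85, adjusted p = 0.0056) with Itgav over all genes, and plasma cell genes rose (median 0.69, adjusted p = 0.014) with Sdc1. Fibroblast markers rose (median 1.2, adjusted p = 0.018) and cardiomyocyte markers fell (median -3.1, adjusted p = 1.4e-05). B cell identity genes lie at the threshold (median -0.39, adjusted p = 0.05), with none over all genes. With an estimated correlation these 9 lists have an adjusted p from 0.31 to 0.77. Leaving out the naive set 1 libraries 1 and 2 ends the calls of the B cell identity (adjusted p = 0.16), plasma (0.058) and fibroblast lists (0.062). Single genes of other lists that rose are Fn1, Flt3, Il7r and Mybl1. Set 1 alone calls 2 genes, and 1117 pass without DT+PFD library 17. With the replicate block 97 pass, with 22 of the 33 named genes.

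How the CD11b-positive gate differs from the CD11b-negative gate was first asked in naive hearts. Spn (ENSMUSG00000051457, chromosome 7, 127132232 to 127137823), which encodes CD43, rose from 5.26 ± 1.26 (SD, n = 8) to 19.2 ± 10.5 (SD, n = 8) CPM (log2 1.85, adjusted p = 0.03, block adjusted p = 0.07). S100a6 stood at 219 ± 130 (SD, n = 8) against 36.4 ± 46.7 (SD, n = 8) CPM (log2 2.55, adjusted p = 0.04, block adjusted p = 0.076), and Cd44 at 345 ± 120 (SD, n = 8) against 125 ± 118 (SD, n = 8) CPM (log2 1.51, adjusted p = 0.031, block adjusted p = 0.07). Siglecg was lower, at 255 ± 149 (SD, n = 8) against 532 ± 294 (SD, n = 8) CPM (log2 -1.16, adjusted p = 0.03, 6 of 8, block adjusted p = 0.068). Itgam, the gene of CD11b, stood at 123 ± 71.1 (SD, n = 8) against 23.7 ± 53.7 (SD, n = 8) CPM and did not pass (adjusted p = 0.24). In total 154 genes were higher and 35 lower (2 immunoglobulin segments).

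The named genes higher in naive CD11b-positive cells are Cd300e, Mgst1, Tnfaip6, Tlcd2, Rab11fip1, Havcr2, Txnrd1, Actg1, Slc2a3 and Vnn3. Cd300e, a receptor of monocytes, stood at 18.8 ± 17.5 (SD, n = 8) against 0.0084 ± 0.0238 (SD, n = 8) CPM (adjusted p = 0.0014, 8 of 8, block adjusted p = 0.0015), and Slc2a3 at 194 ± 89 (SD, n = 8) against 54.4 ± 14.2 (SD, n = 8) CPM. The named genes lower are Cacnb1, Serp2, Nop56, Dpf2, Siglecg, Miip, Slc35f2, Atf7, Scn8a and Hmgn5. B-1 genes were higher as a list (median 1.4, adjusted p = 6.9e-07, 0.055 with an estimated correlation), with Spn, Plscr1 and S100a6 of 10 over all genes and 6 adjusted over the list alone. Its Cd5 stood at 0 to 2.4 against 0 to 3.17 CPM. B cell identity (median -0.72, adjusted p = 1.5e-08), MHC class II (median -0.55, adjusted p = 2.5e-05) and follicular genes (median -0.69, adjusted p = 0.0011) were lower, with 10, 8 and 3 adjusted over the list alone. Ribosomal protein genes were lower too (median -0.35, adjusted p = 1.7e-06). With an estimated correlation these 4 have adjusted p from 0.19 to 0.26.

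Interferon genes (median 1.5, adjusted p = 9.4e-08, adjusted p = 0.089 with an estimated correlation) and cytokine genes (median 1.9, adjusted p = 1.8e-07, adjusted p = 0.089 with an estimated correlation) were higher in naive CD11b-positive cells, with Isg15 the only one over all genes. Immediate early (median 0.79), antigen receptor activation (0.14), plasma (0.56), TGF-beta (0.35), p53 (0.43) and glycolysis genes (0.16) were higher as lists, with adjusted p from 0.089 to 0.34 with an estimated correlation. Monocyte and macrophage markers were higher (median 1.9, adjusted p = 3.2e-16, adjusted p = 0.099 with an estimated correlation), with Ly6c2 of 19 over all genes, as were neutrophil markers (median 3.4, adjusted p = 1.5e-10, adjusted p = 0.099 with an estimated correlation). Markers of dendritic cells (median 2.1), T and NK cells (1.5), cardiomyocytes (2.3), fibroblasts (2.8) and endothelial cells (2.1) were also higher, with adjusted p from 0.099 to 0.26 with an estimated correlation. Further single genes were Itgb1, Cd209a and Ppbp.

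The libraries labelled naive set 1, CD11b-positive 1 and CD11b-negative 2, stand apart in this comparison. Itgam is at 1.02 CPM in the first, against 47.1 to 224 CPM in the other naive CD11b-positive libraries, and at 157 CPM in the second, against 2.08 to 9.13 CPM in the other CD11b-negative libraries. Without both, a choice made after seeing the data, 1514 genes are higher and 706 lower, Itgam passes (log2 4.78, adjusted p = 7.3e-06), Cd19 passes (-1.14, adjusted p = 0.0011), and the B-1 list has an adjusted p = 0.00065 with an estimated correlation. The medians are then 7.2 for monocyte, 8.4 for neutrophil, 3.3 for dendritic cell markers, and 3.1 for cytokine genes, and the glycolysis list no longer passes (adjusted p = 0.14). The myeloid score tracks the gate, so 0 calls with it as covariate leave myeloid RNA open for Spn, Plscr1 and S100a6. With a replicate block 28 genes pass, with 11 of the 29 named genes, set 1 alone calls 0, and leaving out any of 13 libraries moves the count over 1.5 times, from 4 to 1452.

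**Figure D2:**
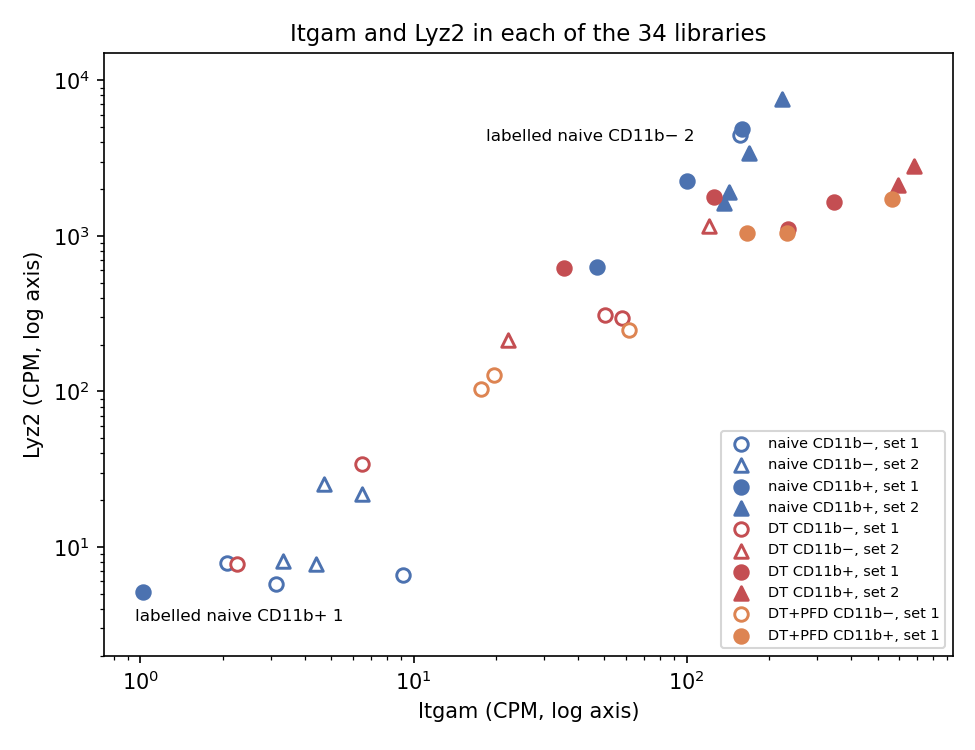
Itgam against Lyz2 (both in CPM, log scales) for 34 libraries, by gate and condition. The naive set 1 libraries labelled 1 and 2 (Itgam 1.02 and 157 CPM) lie among the libraries of the other gate.

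In injured hearts the CD11b-positive gate had 345 genes higher and 190 lower than the CD11b-negative gate, with 17 immunoglobulin segments higher and 3 lower. Igha, the IgA heavy chain constant region, stood at 13700 ± 9270 (SD, n = 6) against 639 ± 602 (SD, n = 6) CPM (log2 4.69, adjusted p = 0.012) and Jchain, which joins IgA and IgM units, at 4680 ± 2370 (SD, n = 6) against 318 ± 343 (SD, n = 6) CPM (log2 4.24, adjusted p = 0.018). Mzb1 (ENSMUSG00000024353, chromosome 18, 35647266 to 35649367), a chaperone in antibody secretion, stood at 704 ± 477 (SD, n = 6) against 232 ± 58 (SD, n = 6) CPM (log2 1.59, adjusted p = 0.0049). Hilpda was higher, at 221 ± 160 (SD, n = 6) against 65.0 ± 27.4 (SD, n = 6) CPM (log2 1.70, adjusted p = 0.0014, 6 of 6, block adjusted p = 0.0026). Cd19 was lower, at 865 ± 532 (SD, n = 6) against 1850 ± 783 (SD, n = 6) CPM (log2 -1.15, adjusted p = 0.024, 6 of 6, block adjusted p = 0.044). Ccr7, a homing receptor for lymph nodes, was lower, at 839 ± 451 (SD, n = 6) against 2050 ± 756 (SD, n = 6) CPM (log2 -1.28, adjusted p = 0.023).

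The other named genes higher in DT CD11b-positive cells are Lrrfip1, Plp2, Igkc, Ssr4, Bckdk, Tmed10, Ppib, Gapdh and Fkbp2, of which Ssr4, Tmed10, Ppib and Fkbp2 act in the secretory pathway. The named genes lower are Cdc25b, Card6, Sfn, Plcxd2, Acp6, Zcchc2, Fam134c, Neil1, Acat2 and Ganc. Plasma cell genes were higher (median 1.8, adjusted p = 8.9e-09, adjusted p = 0.021 with an estimated correlation), with 7 of 15 over all genes, among them Igha, Jchain, Mzb1 and Derl3, and 8 adjusted over the list alone. B-1 genes were higher (median 1.8, adjusted p = 1.2e-06, adjusted p = 0.021 with an estimated correlation), with Spn, Plscr1 and Ctla4 of 10 over all genes and 7 adjusted over the list alone. Glycolysis genes were higher (median 0.67, adjusted p = 1.2e-09, adjusted p = 0.019 with an estimated correlation), with 9 of 16 over all genes, such as Gapdh, Tpi1, Ldha and Hk2, and 10 adjusted over the list alone. p53 genes were higher (median 0.59, adjusted p = 7e-04, adjusted p = 0.019 with an estimated correlation), with Bax over all genes.

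B cell identity (median -0.87, adjusted p = 2.3e-09) and follicular genes (median -1.2, adjusted p = 1.2e-06) were lower in DT CD11b-positive cells. Cd19 and Cd72 of 17, and Ighd, Ccr7 and Cxcr5 of 9, were lower over all genes. MHC class II genes were lower (median -0.43, adjusted p = 0.0011) with H2-Ob over all genes, and ribosomal genes were lower (median -0.18, adjusted p = 0.048). Oxidative phosphorylation genes were higher (median 0.37, adjusted p = 0.00092) with Ndufb8 and Sdhb. Monocyte markers were higher (median 2.3, adjusted p = 2.3e-09) with Ly6c2, and neutrophil markers were higher (median 4.2, adjusted p = 5.9e-07) with Cxcr2. With an estimated correlation these 7 lists have an adjusted p from 0.14 to 0.61. Lists of interferon, cytokine, activation, immediate early, NF-kB and TGF-beta genes and of dendritic, cardiomyocyte, fibroblast, endothelial and pericyte markers were higher as well, with adjusted p from 0.14 to 0.48 with an estimated correlation. Further single genes were Cd44, Nr4a2, Itgb1, Itgb2, Icam1, Basp1 and Cd209a, which were higher, and Bcl6 and Relb, which were lower. With the myeloid score as a covariate, chosen after seeing the data, 14 genes pass. Set 1 alone calls 0, and with the replicate block 268 pass, with 36 of the 50 named genes.

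**Figure D3:**
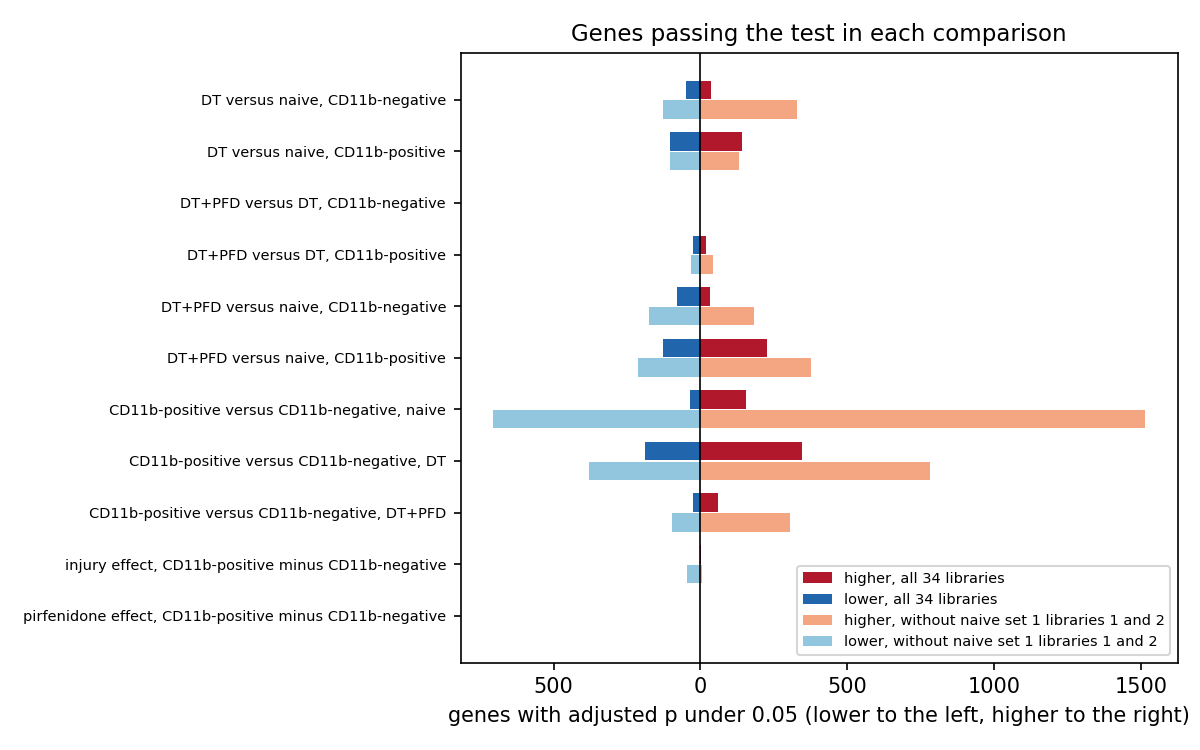
Number of genes higher and lower in each comparison (bars), with all 34 libraries and without the naive set 1 libraries 1 and 2. The naive gate comparison goes from 189 to 2220 genes.

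In DT+PFD hearts the CD11b-positive gate had 60 genes higher and 25 lower, with 2 immunoglobulin segments higher. Capg (ENSMUSG00000056737, chromosome 6, 72544391 to 72562983), an actin-capping protein, stood at 288 ± 53.7 (SD, n = 3) against 74.8 ± 29.7 (SD, n = 3) CPM (log2 1.95, adjusted p = 0.0047, 3 of 3). Hilpda stood at 179 ± 31.3 (SD, n = 3) against 38.7 ± 10.8 (SD, n = 3) CPM (log2 2.21, adjusted p = 0.0047, 3 of 3, block adjusted p = 0.0047). Xbp1, the transcription factor of the secretory program in plasma cells, stood at 68.6 ± 30.6 (SD, n = 3) against 8.31 ± 4.88 (SD, n = 3) CPM (log2 3.04, adjusted p = 0.041, block adjusted p = 0.083). Further named genes higher are Psmd6, Ckap4, Psmd14, Ppib, Atp5g1, Reep5, Tmed10, Bckdk and Gapdh. Those lower are Pigh, Kctd18, Usf1, Smagp, Rnf31, Trib3, Sugp2, Ralgapa2, Nat2 and Zbtb24.

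Plasma cell genes (median 3, adjusted p = 3.9e-09, adjusted p = 0.042 with an estimated correlation) and B-1 genes (median 1.5, adjusted p = 5.4e-06, adjusted p = 0.042 with an estimated correlation) were higher in the DT+PFD gate comparison, with 9 of 15 and 7 of 10 adjusted over the list alone. Glycolysis genes were higher (median 0.64, adjusted p = 2.9e-06, adjusted p = 0.091 with an estimated correlation), with Gapdh over all genes and 10 of 16 adjusted over the list alone. Fibroblast (median 3.9, adjusted p = 9.8e-07, adjusted p = 0.23 with an estimated correlation) and monocyte markers (median 2.4, adjusted p = 7.9e-06, adjusted p = 0.38 with an estimated correlation) were higher. Markers of neutrophils (median 3.9), erythroid cells and platelets (2.8), pericytes (2.5), cardiomyocytes (2.2), endothelial cells (2.1) and T and NK cells (1.9) also were, with adjusted p from 0.0015 to 0.046, and from 0.38 to 0.47 with an estimated correlation. The pericyte call ends without the naive set 1 libraries 1 and 2 (adjusted p = 0.055). Cytokine (median 3.3), activation (1.2), TGF-beta (0.62), oxidative phosphorylation (0.47) and immediate early genes (0.39) were higher as lists, with adjusted p from 0.22 to 0.38 with an estimated correlation. Follicular (median -0.86, adjusted p = 0.0043, adjusted p = 0.38 with an estimated correlation) and B cell identity genes (median -0.51, adjusted p = 0.018, adjusted p = 0.52 with an estimated correlation) were lower. The call becomes 1 without DT+PFD CD11b-negative library 22 and 583 without CD11b-positive library 17. A replicate block leaves 20 genes, with 15 of the 22 named genes.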

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

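The tests on Itgam levels, on carried-over RNA, on the ratios of Arg1 and Spp1 to Lyz2, on the fibroblast score and on the myeloid score of the glycolysis list, and the splits that keep the sets, were chosen only after the results were seen. The test of exchanged labels, the test of the glycolysis list without the naive CD11b-positive libraries of set 2, and the counts over splits that ignore the set or are between gates were written down before they were run. Measures of the libraries were compared within groups by Dixon's test, 84 tests over 21 measures, which marked 13 values. Chance alone marks about 1 in 20 groups.

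The first pattern is that the naive set 1 libraries labelled CD11b-positive 1 and CD11b-negative 2 stand against their gate labels. In the library labelled CD11b-positive 1, Itgam is at 1.02 CPM (others 47.1 to 224), Lyz2 at 5.17 (632 to 7550), Il1b at 2.52 (224 to 2320), and the fibroblast score at 0.83 (4.38 to 6.66). In the library labelled CD11b-negative 2, Itgam is at 157 CPM (others 2.08 to 9.13), Lyz2 at 4450 (5.77 to 25.3), Il1b at 414 (2.37 to 12), Tnf at 179 (3.71 to 22.7) and Ccl7 at 137 (0.528 to 1.1). A score free of myeloid genes, B-1 minus follicular genes, is -6.85 in the library labelled CD11b-positive 1 and -4.04 in the library labelled CD11b-negative 2, a difference of 2.81, where CD11b-negative 4, 6 and 8 span -6.88 to -5.92 and CD11b-positive 3, 5 and 7 span -4.42 to -3.55. Exchanged labels could give this. Myeloid cells in library 2 alone leave open why Itgam is low in library 1 (46.1 times under the lowest other naive CD11b-positive library). That gap defined the pattern, so it is no test of those cells.

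In the library labelled CD11b-negative 2 the monocyte and macrophage score is 8.6 (others 2.02 to 3), the B cell identity score 8.72 (9.47 to 9.6) and the plasma cell score 6.47 (4.38 to 5.29). The labels were kept as deposited in every fit, and the fits without both libraries stand beside them. Cd79a is at 1200 CPM in DT CD11b-negative library 10 (others 2420 to 3600), which was not tested further.

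The second pattern is the rise of genes such as Arg1, Spp1 and Il7r after injury in the CD11b-negative gate, where RNA from myeloid cells could be a source although both the CD19 and the CD11b gate should remove them. The monocyte and macrophage list was fixed beforehand, has 19 genes, none in another list and 7 with at least 10 CPM in naive CD11b-negative libraries, and its Lyz2 stands at 337 ± 425 (SD, n = 6) CPM in DT CD11b-negative against 1679 ± 766 (SD, n = 6) CPM in DT CD11b-positive libraries, a share of 20.1 percent that spans 10.2 to 24 percent when 1 DT CD11b-negative library is left out. Taking this share and the makeup of the CD11b-positive DT libraries, 14 of the 37 genes rose by over 3 times the carried amount above the naive libraries other than that labelled 2 (the same 14 above all 8), also without any 1 library, which is against myeloid RNA of that makeup as the source of all, Il7r (10 times), Pde2a (6.13) and Ptpn22 (4.83) among them. The other 23, such as Timp1 (1.95) and Serpina3n (1.21), may be carried over. For Arg1 (1.27) the median ratio to Lyz2, 0.219, lies within 0.00426 to 0.321 of CD11b-positive DT libraries, so Arg1 may be carried over. For Spp1 the ratio of 1.97, against 0.136 to 1.71, leaves this open. With the fibroblast score as a covariate 26 of the 37 pass (median log2 1.95 against 2.1), which is against a larger share of fibroblast RNA of unchanged makeup, but fibroblasts changed by injury stay open.

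Of these tests, the myeloid score as a covariate was tried first, and 24 of the 37 genes passed with a median log2 change of 2.08. It was replaced by the estimate of carried-over RNA because naive CD11b-positive libraries other than the one labelled 1 hold Lyz2 at 632 to 7550 CPM with little Arg1. The bound of 3 was picked after the ratios were seen. A joint test of Arg1 and Spp1 was first against the explanation through Spp1, and was then divided by gene with a looser bound. The fibroblast list has 10 genes, none in another list and 2 with at least 10 CPM in naive CD11b-negative libraries, and the CD19 gate should remove such cells. The explanations by fibroblast RNA and by myeloid RNA for the glycolysis list were narrowed to unchanged makeup after the covariate results were seen.

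The third pattern is the rise of glycolysis and hypoxia genes after injury in the CD11b-positive gate, next to a mitochondrial share of 23.8 ± 5.47 (SD, n = 4) percent in the naive libraries of set 2. Without those libraries the median log2 change of the list is 0.63 against 0.67, with adjusted p = 6.4e-06 in limma's camera, although 0 of its genes then pass singly. With the mitochondrial share as a covariate in all libraries the median is 0.59 and 2 of the 16 genes pass against 6, so single calls depend on this share while the median moves little. With the myeloid score as a covariate the median is 0.63 and 6 genes pass, which is against a larger share of myeloid RNA of unchanged makeup, but a change within myeloid cells stays open. Of the 16 genes 15 have at least 10 CPM in naive CD11b-negative libraries, and their source stays open.

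Of all genes, 3 differ between the gates in their response to injury. Hilpda differs by 1.94 (SE 0.32, adjusted p = 0.015 with edgeR), with changes of 2.48 in the CD11b-positive and 0.548 in the CD11b-negative gate. Igkv1-117 differs by 3.47 (SE 0.59, adjusted p = 0.015), with 2.11 and -1.36, and Igkv4-90 by 6.97 (SE 1.3, adjusted p = 0.034), with 5.3 and -1.66.

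Splits as high are few for the gates in naive and DT hearts (2 of 60 with the real one). This is against chance in the grouping, though another split calls 311 against 189 and 2091 against 535 genes. All splits keep the sets, and set 1 alone calls 0 in each. Chance is not excluded for the 2 injury comparisons. Splits that ignore the set are rarely as high (86 against 413, 2 of 60, in the CD11b-negative and 247 against 31, 1 of 60, in the CD11b-positive gate), but of the splits that keep the sets 4 of 60 are as high in each gate (highest 434 and 557). Set 1 alone calls 0 and 3 genes there and the replicate block 28 and 22. The same is true for DT+PFD against naive CD11b-positive cells (355 against 197, 1 of 60, and against 623, 2 of 35, with the sets kept) and for the difference of the injury effect (3 against 2, 1 of 60, and against 8, 3 of 60). Chance cannot be excluded with either kind of split for DT+PFD against DT CD11b-negative (914 at an unadjusted p under 0.05 against 1523, 13 of 60 and 14 of 35) and CD11b-positive cells (42 against 613, 8 of 60 and 8 of 35), DT+PFD against naive CD11b-negative cells (110 against 268, 3 of 60, and 326, 7 of 35) and the difference of the pirfenidone effect (1092 at an unadjusted p under 0.05 against 3481, 37 of 60, and 4033, 50 of 60). For the gates in DT+PFD hearts 10 splits are too few (85 against 2, 1 of 10). Splits with over 3 times the real count (413, 434, 613, 2091, 3481 and 4033 genes) point to a structure of the samples. The split with 2091 genes puts DT CD11b-negative library 10 in place of CD11b-positive library 13, and those with 613, 3481 and 4033 hold DT CD11b-positive library 13 in place of DT+PFD library 17. In all 4 comparisons with naive hearts the highest split that keeps the sets moves the naive library labelled 1 or 2 to the other group.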

How the results depend on the processing

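The covariates, the pairing of consecutive set 1 numbers, the fits without the naive libraries 1 and 2 and the fit without the naive CD11b-positive libraries of set 2 were chosen only after the results were seen. Comparisons are named here by their groups, and the values are numbers of genes that pass. With all libraries they are 86 and 247 for DT against naive in CD11b-negative and CD11b-positive cells, 0 and 42 for DT+PFD against DT, 110 and 355 for DT+PFD against naive, 189, 535 and 85 for the gates in naive, DT and DT+PFD hearts, and 3 and 0 for the gate differences of injury and pirfenidone. The cause of a change was not tested unless it is given. DESeq2's size factors, robust=FALSE and the stricter filter kept all 11 counts within 1.5 times. The rule on library quality removed 0 libraries and is void.

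Of the 245 passing calls of named genes, 5182 repeats over all settings kept direction and threshold, 1986 kept the direction without passing, and 1 reversed. The reversal is Nipal4 in DT+PFD against naive CD11b-positive cells, with a log2 change of -0.192 without DT+PFD library 21, against 7.65 without library 19. Numbers of genes were within 1.5 times in 88 repeats and outside in 110, and numbers of lists in 61 and 27. Simulated recovery was 16 percent at a fold of 2 in DT against naive CD11b-negative cells. The simulation varied neither depth nor spread, so by itself it does not tell which of them limits the calls.

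With DESeq2 more genes pass. DT against naive gives 381 in CD11b-negative and 714 in CD11b-positive cells, DT+PFD against DT 104 and 519, and DT+PFD against naive 622 and 1253. The gates differ in 1175 genes in naive, 1464 in DT and 1079 in DT+PFD hearts, and the gate differences of injury and of pirfenidone give 42 and 91. With limma-voom and quality weights DT against naive CD11b-negative cells gives 677, DT+PFD against DT 4 and 0, DT+PFD against naive 1313 and 53, the gates 2571 in naive and 3085 in DT hearts, and the injury difference 0.

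Without the set term DT against naive CD11b-negative cells gives 47 genes and the gates 208 in DT and 11 in DT+PFD hearts. Set 1 alone gives 0 and 3 for DT against naive, and 0 for DT+PFD against DT in CD11b-positive cells. It gives 0 and 2 for DT+PFD against naive, and 0 for the injury difference. The gates give 0, 0 and 2 in naive, DT and DT+PFD hearts. The smaller set 2 alone gives 339 for DT against naive CD11b-negative, 2707 for the gates in naive hearts and 1 for the injury difference. With only the groups compared in the fit DT against naive gives 219 and 32, DT+PFD against DT CD11b-positive 0, DT+PFD against naive 340 and 13, the gates 19, 272 and 183, and the injury difference 1.

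The replicate block gives 28 and 22 for DT against naive, 7 for DT+PFD against DT in CD11b-positive cells, 39 and 97 for DT+PFD against naive, 28, 268 and 20 for the gates in naive, DT and DT+PFD hearts, and 1 for the injury difference. By construction the block takes up the set 2 difference between naive and DT. With consecutive numbers of set 1 paired in the block as well, the gates give 346, 433 and 25 genes in naive, DT and DT+PFD hearts, of which 95, 338 and 23 are among those called in the report, and the injury and pirfenidone differences give 0. Beyond these counts the set 2 block ended 112 of the 245 calls of named genes and turned none.

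Testing against a fold of 1.5, a stricter question, gives 9 and 23 for DT against naive, 16 for DT+PFD against DT CD11b-positive, 5 and 91 for DT+PFD against naive, 12, 6 and 9 for the gates, and 0 for the injury difference. The deposited score with limma, on 6500 genes, gives 139 for DT against naive CD11b-negative, 167 for DT+PFD against DT CD11b-positive, 316 and 540 for DT+PFD against naive, 1002 and 193 for the gates in DT and DT+PFD hearts, and 0 for the injury difference. Without a filter on low counts DT against naive CD11b-positive gives 138, DT+PFD against DT CD11b-positive 21, DT+PFD against naive CD11b-positive 193, the gates 80, 324 and 23, and the injury difference 1.

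Without the naive set 1 libraries 1 and 2 DT against naive CD11b-negative gives 455 genes, DT+PFD against DT CD11b-positive 75, DT+PFD against naive 360 and 592, the gates 2220, 1162 and 401, and the injury difference 51. Set 1 alone without them gives 0 and 2 for DT against naive, 0 for DT+PFD against DT CD11b-positive, 1 and 2 for DT+PFD against naive, 0 and 4 for the gates in DT and DT+PFD hearts, and 0 for the injury difference. Without the naive CD11b-positive libraries of set 2 DT against naive CD11b-positive gives 50, DT+PFD against naive CD11b-positive 76, the gates 12 in naive and 43 in DT+PFD hearts, and the injury difference 0.

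With the myeloid score as a covariate DT against naive CD11b-positive gives 390 genes, DT+PFD against DT CD11b-negative 1, DT+PFD against naive 243 and 627, the gates 0, 14 and 35, and the injury difference 5. With the mitochondrial share as a covariate DT against naive CD11b-positive gives 116, DT+PFD against naive CD11b-positive 112 and the gates in naive hearts 45. With the fibroblast score DT against naive CD11b-negative gives 102, of which 54 are among the 86.

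Numbers of lists that pass camera's test with its preset correlation are 12 and 13 for DT against naive, 9 and 3 for DT+PFD against DT, 12 and 10 for DT+PFD against naive, 20, 22 and 18 for the gates, 4 for the injury difference and 0 for the pirfenidone difference. With an estimated correlation they are 0 and 3, 0 and 0, 2 and 1, 0, 4 and 2, and 0 for the injury difference. With fry they are 5 and 8 for DT against naive, 0 and 0 for DT+PFD against DT, 3 and 4 for DT+PFD against naive, 11 and 5 for the gates in DT and DT+PFD hearts, and 1 for the injury difference. Without the set term 5 lists pass for DT+PFD against DT CD11b-positive, and set 1 alone has 10 for the gates in naive hearts. With the myeloid score 4, 10 and 10 pass for the gates and 1 for the pirfenidone difference, and without the naive libraries 1 and 2 the gate differences of injury and pirfenidone have 11 and 2. The divided covariance of the injury and pirfenidone effects over called genes alone is -0.00575 (SD 0.921 over divisions) in CD11b-negative and -0.179 (SD 0.494) in CD11b-positive cells, and it is void because those genes were called with both parts of the DT libraries.

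Leaving out each library in turn, DT against naive gives 30 to 372 genes in CD11b-negative cells. It is 372 without naive set 1 library 2 and 30 without DT set 2 library 1, and it also moves over 1.5 times without naive set 1 library 8 (50), naive set 2 libraries 5a (49), 6a (54) and 8a (57), and DT libraries 10 (42) and 16 (51). In CD11b-positive cells the range is 127 to 321, with 142 without naive set 1 library 3, 146 without naive 5a, 151 without DT library 9, and 127 and 132 without DT set 2 libraries 1 and 2. DT+PFD against DT stays at 0 in CD11b-negative cells and spans 4 to 831 in CD11b-positive cells, with 26 without DT set 2 library 2, and 831, 4 and 17 without DT+PFD libraries 17, 19 and 21.

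DT+PFD against naive spans 4 to 313 in CD11b-negative cells when 1 library is left out. It is 313 and 46 without naive set 1 libraries 2 and 8, and 8, 4 and 26 without DT+PFD libraries 18, 20 and 22. In CD11b-positive cells it spans 145 to 1117, with 226 without naive library 7 and 1117, 148 and 145 without DT+PFD libraries 17, 19 and 21. The gates in DT+PFD hearts span 1 to 583, with 583, 17 and 45 without CD11b-positive libraries 17, 19 and 21 and 12, 3 and 1 without CD11b-negative libraries 18, 20 and 22.

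The gates in naive hearts span 4 to 1452 with 1 library left out. The values are 917, 86 and 43 without CD11b-positive set 1 libraries 1, 5 and 7, 118 and 34 without 7a and 8a, 1452, 27, 18 and 26 without CD11b-negative set 1 libraries 2, 4, 6 and 8, and 16, 15, 14 and 4 without 5a to 8a. The gates in DT hearts span 104 to 1131, with 351, 885 and 330 without CD11b-positive libraries 9, 13 and 15, 308 and 285 without set 2 libraries 1 and 2, 1131, 271, 183 and 215 without CD11b-negative libraries 10, 12, 14 and 16, and 104 without set 2 library 1. The injury difference spans 0 to 6, with 1 and 6 without DT CD11b-positive libraries 9 and set 2 library 2, and 0 and 1 without DT CD11b-negative set 2 libraries 1 and 2. The pirfenidone difference spans 0 to 229, with 2 and 1 without DT CD11b-positive libraries 15 and set 2 library 1, and 229 and 1 without DT+PFD CD11b-positive libraries 17 and 19.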

Other observations

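The 18 genes of the glucocorticoid list were chosen after the injury results were seen, and so was every test of this part. Fkbp5 and Il7r, both among the genes that rose after injury in the CD11b-negative gate, are known targets of the glucocorticoid receptor, which led to the hypothesis of a glucocorticoid response in injured hearts. The whole list rose in the CD11b-negative gate (camera p = 2.6e-08, p = 0.0025 with an estimated correlation in limma) and in the CD11b-positive gate (p = 0.00011, p = 0.026 with an estimated correlation, and 0.055 without the naive set 1 libraries 1 and 2). Since the list was drawn up around Fkbp5 and Il7r, the test was repeated with the 16 other genes. Of these 12 were higher in DT CD11b-negative cells (median log2 0.9, p = 0.048 with an estimated correlation in limma) and 11 in DT CD11b-positive cells (median 0.52, p = 0.16). The larger of both values, 0.16, leaves the hypothesis undecided.

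Under pirfenidone the 16 genes have a median log2 change of -1 in CD11b-negative cells, with 4 higher (p = 0.038 with an estimated correlation in limma), and of -0.64 in CD11b-positive cells, with 2 higher (p = 0.11). The DT libraries are in both effects, so a higher value after injury makes a lower one under pirfenidone more frequent by chance. With set 1 alone the 16 genes have a median of 1.1 and 0.87 after injury in the 2 gates, and neither passes with an estimated correlation.

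Xist stands at 65.52 to 457.7 CPM and the Y-linked Ddx3y at 0 to 0.1001 CPM over the 34 libraries.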
